A study of Harpegnathos saltator with 12 samples.

How the data were processed

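Kr-h1 ChIP-seq and input libraries were made from the central brain of Harpegnathos saltator workers and gamergates, with 3 samples per caste for ChIP and 3 for input. Groups were taken from the sample titles. Per the labels' protocols, callow females aged 5 days were set up in groups of 25 with 3 males and no reproductive female, and the colony was collected 120 days after isolation, when mature oocytes marked the gamergates. The labels also mention earlier collections and do not say per sample which day applies. Per the labels' protocols, chromatin was crosslinked for 5 minutes and sonicated for 12 minutes, 10% of the lysate was kept as input, and libraries received 13 PCR cycles for Kr-h1 ChIP and 5 for input. This difference in amplification applies to every ChIP and input pair.

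The submitters' processing notes name bcl2fastq, Trimmomatic, Bowtie2 2.2.6, SAMtools and MACS2 2.1.1.20160309, without their settings or order. The genome build, the peak threshold, the treatment of duplicate reads and whether samples or castes were pooled for peak calling are not given in the sources used here. The authors deposited 1 peak list with 4 columns: per the file headers these are scaffold, start, end and fold enrichment, a linear ratio. No column carries a sample, a caste, a count, a summit or a q-value. The lowest fold in the list is 3.00, so a lower limit of 3 is a property of the list. Whether starts count from 0 or from 1 is not given, so starts may be off by 1 bp, and width is end minus start. No intervals overlap and none is repeated.

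Most of the analysis fixed before the data were examined needed values per sample or a gene annotation and sequence of the assembly the peaks are placed on, and was not done here. This covers the worker against gamergate comparison, the location of peaks relative to genes, the fixed gene lists, GC content and sequence motifs. A table of genes from the Hsal_v8.6 assembly was not used, because it gives no scaffold for its genes and the peaks name no build; no gene is therefore assigned to a peak. Of the rule for named genes, fixed before the data were examined, the 15 peaks of highest fold were kept. The rule's 5 genes with most peaks were replaced by the 5 scaffolds with most peaks, a substitute not fixed beforehand. Peak number, width and fold were fixed beforehand. So were the lists at or above the median fold, of the 1000 strongest peaks and merged at 500 bp. The other lists of peaks and scaffolds were chosen after seeing the data. So were the correlation of width with fold and the spacing, neighbour and step analyses.

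From the list, widths, gaps and shares were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Medians and shares have 95% percentile intervals from 1000 bootstrap draws of whole scaffolds; these describe variation along the genome, not between animals. Because the list gives no counts, no counting interval was computed. For spacing, the outermost peaks of each scaffold stayed in place and the others were placed at random between them, 1000 times, never closer than 182 bp, the smallest gap in the list. Scaffolds with fewer than 3 peaks do not enter. Sequence in which no read can be mapped was not masked in these placements. Neighbour correlations and the comparison of grouped with solitary peaks were tested against 1000 shuffles of fold within scaffolds. All p-values are two-sided permutation values. Tested on simulated data, the spacing test passed 0.05 in 5 of 100 lists of 5033 randomly placed peaks and in 20 of 20 lists in which 10% of gaps were shortened. The random lists were drawn by the same rule as the placements, so their rate checks the calculation only. It does not cover unmappable or peak-free sequence. Each simulated list was tested against fewer placements than the real list. Alternatives were a stricter fold (at or above the median, 10 or more, or the 1000 strongest), merging of peaks less than 500 bp or 1 kb apart, other distance limits, scaffolds broken at gaps over 100 kb, and subsets of peaks and scaffolds.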

Results

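Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding of Kr-h1 in the central brain of the ant Harpegnathos saltator. Kr-h1 (Krüppel homolog 1) is a zinc-finger transcription factor known as a response gene of juvenile hormone. In this species a worker kept away from reproductive females can become a gamergate, a worker that lays eggs. The series holds 12 samples in 4 groups of 3: Kr-h1 ChIP from workers, Kr-h1 ChIP from gamergates, and the input chromatin of each caste. The design asks where Kr-h1 sits on brain chromatin relative to input, and whether the castes differ. The values available here are 1 list of peaks for the whole series, each with a position and a single fold enrichment. No value in the list belongs to 1 sample or 1 caste, so binding in workers was not compared with binding in gamergates, and no replicate error can be attached to any peak. Read depth per sample is likewise unknown. All fold enrichments below are the authors' own values, and all positions are on the scaffolds of the authors' assembly, whose build is not given in the sources used here.

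Kr-h1 was enriched over the peak caller's background at 5033 peaks on 393 scaffolds, and these peaks covered 4.08 Mb. Most enrichments were modest. The median fold enrichment was 4.73, with a 95% interval of 4.64 to 4.83 from resampling whole scaffolds. No peak lay below a fold of 3, and 1794 peaks (35.6%, interval 34.2 to 37.0%) lay between 3 and 4. A smaller set was far stronger: 946 peaks (18.8%, interval 17.4 to 20.2%) reached a fold of 10, 356 peaks (7.07%, interval 6.23 to 7.94%) reached 20, and 34 peaks reached 50. Of the peaks, 63.2% lay on the 99 scaffolds that held 20 or more, and 54 scaffolds held only 1.

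The peak with the highest enrichment lay on scaffold612 from 542849 to 544138, with a fold of 96.2 over 1289 bp. It was followed by a peak on scaffold37 from 873146 to 875109, with a fold of 77.7 over 1963 bp, and by one on scaffold250 from 697627 to 698435, with a fold of 74.4 over 808 bp. The next were scaffold213 from 889574 to 891055 with a fold of 68.7 and scaffold128 from 1259959 to 1260705 with a fold of 68.0. The peak on scaffold58 from 1394418 to 1395268 had a fold of 65.8 and stood alone, its nearest neighbour being 254432 bp away. The peaks on scaffold91 from 499498 to 500339, on scaffold119 from 322540 to 323280 and on scaffold109 from 398898 to 399844 had folds of 65.8, 65.7 and 65.0. Scaffold18 held a pair of the 15 strongest peaks side by side: 1467234 to 1468510 with a fold of 65.2 and 1470119 to 1473954 with a fold of 62.2, separated by 1609 bp. The remaining members of the 15 lay on scaffold467 from 105606 to 106674, scaffold47 from 1955261 to 1956691, scaffold374 from 376136 to 376898 and scaffold113 from 36716 to 37597, with folds of 64.3, 64.2, 62.0 and 61.4. The 15 peaks fell on 14 scaffolds, and 5 of them had another peak within 5 kb.

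Peaks were mostly narrow, and stronger peaks were wider. The median width was 689 bp (interval 677 to 700 bp), the middle of the distribution ran from 498 to 997 bp, and the range was 181 to 4872 bp. Ordered by fold, the weakest 1268 peaks had a median width of 539 bp and the strongest 1255 had a median of 862 bp. Peaks of 2000 bp or more made up 0.789% of the weakest set and 6.69% of the strongest. Across the 5033 peaks the rank correlation of width and fold was 0.37 (Pearson's r of the log2 values 0.36). Both had a two-sided permutation p of 0.0001, the smallest that 10000 resamples can give. Peaks are not independent replicates, so this p describes the list and not the animals. Width and fold also come from the same peak call, so the p cannot tell a link in binding from one made by the calling. The widest peak lay on scaffold124 from 232132 to 237004, with a fold of 14.5 over 4872 bp. The scaffold18 peak of 3835 bp was the only member of the 10 widest that was also among the 15 strongest. Scaffold104 held a pair of wide peaks with folds not far above the list's median of 4.73: 101139 to 104974 with a fold of 4.79 and 120049 to 123828 with a fold of 5.48.

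**Figure D1:**
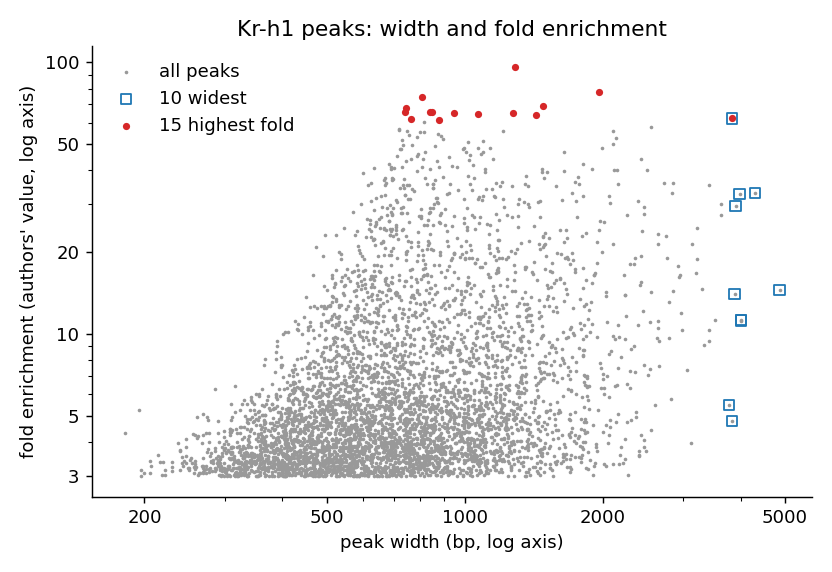
Each point is 1 peak of the list, with its width in bp on the horizontal log axis and the authors' fold enrichment on the vertical log axis; red points are the 15 peaks of highest fold and blue squares the 10 widest. Width rises with fold (rank correlation 0.37), and 1 peak, on scaffold18, belongs to both sets.

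The scaffold with most peaks was scaffold51, with 71 peaks up to position 2349287, a median fold of 4.85 and 14 peaks of fold 10 or more. Scaffold38 and scaffold58 each held 68 peaks, with median folds of 4.88 and 5.27. Scaffold93 held 66 peaks and reached the highest coordinate of any peak, 3301100. Scaffold8 held 61 peaks. Up to the last peak these scaffolds carried 30.2, 22.0, 22.3, 20.0 and 24.1 peaks per Mb, in that order. Across the 393 scaffolds, peak number rose with the position of the last peak (rank correlation 0.84). The list gives no scaffold lengths, and the last of many peaks tends to lie further along, so part of this correlation is built in. It cannot show how far the ranking follows scaffold length. The ranking by number is not one of density. Some scaffolds with fewer peaks were denser up to their last peak, such as scaffold9 with 32 peaks at 49.4 per Mb and scaffold252 with 47 at 45.2 per Mb.

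Peaks lay closer to one another than random placement within scaffolds gave. Of 4602 gaps between neighbouring peaks on scaffolds with at least 3 peaks, 23.1% were under 5 kb. In 1000 random placements that kept the outermost peaks of each scaffold, the share was 11.9% ± 0.432 (SD over placements), and the highest was 13.5%. The two-sided permutation p was 0.002, the smallest these placements can give. The excess was smaller, 26.6% against 20.3% ± 0.557, when gaps over 100 kb were taken out of the space in which peaks were placed. On the scaffolds with at least 3 peaks, neighbours within 5 kb of each other formed 799 groups of 2 or more peaks, against 471 ± 16.2 under random placement. The whole list holds 808 such groups. There were 181 groups of 3 or more (62.2 ± 6.99) and 18 groups of 5 or more (1.44 ± 1.2), each with a permutation p of 0.002. The placements for groups left the gaps over 100 kb in. Groups were not counted in placements without those gaps, where the excess of short gaps was smaller.

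**Figure D2:**
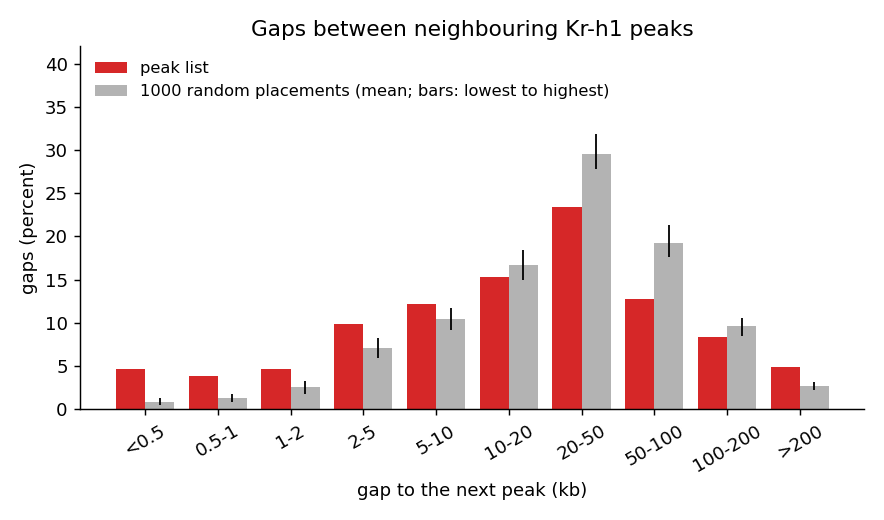
Share of gaps between neighbouring peaks, in percent, by gap length in kb; red bars are the peak list, grey bars the mean of 1000 random placements, and black lines run from the lowest to the highest placement. Gaps under 0.5 kb made up 4.72% of the list against 0.84% in the placements, and gaps over 200 kb made up 4.87% against 2.67%.

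The group with most peaks lay on scaffold37 from 858242 to 882236. It held 9 peaks within 24.0 kb, among them the second strongest of the list. That peak, with a fold of 77.7, was joined on its higher-coordinate side by peaks of fold 48.2 (878351 to 879422) and 24.1 (880275 to 882236), while the other 6 had folds of 3.04 to 9.67. Scaffold285 held a group of 7 peaks from 336719 to 355515 with a highest fold of 43.7. Counted by peak centre, it also held the 100-kb window with most peaks, 322662 to 422358, with 19 peaks, a median fold of 8.11 and a highest fold of 46.8. The densest window of a random placement held 13.8 ± 1.23 peaks on average and 17 at most (permutation p of 0.002). These placements also left the gaps over 100 kb in. Scaffold25 held a group of 7 peaks from 2663469 to 2682762 with a highest fold of 30.9. A window on scaffold113 from 27823 to 128110 held 18 peaks, including the peak of fold 61.4. At the other extreme, no peak was listed for 984 kb on scaffold846, between 286965 and 1271091, a gap within the range that placements gave (permutation p of 0.25). These groups, windows, wide peaks and the gap were chosen after their values were seen.

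**Figure D3:**
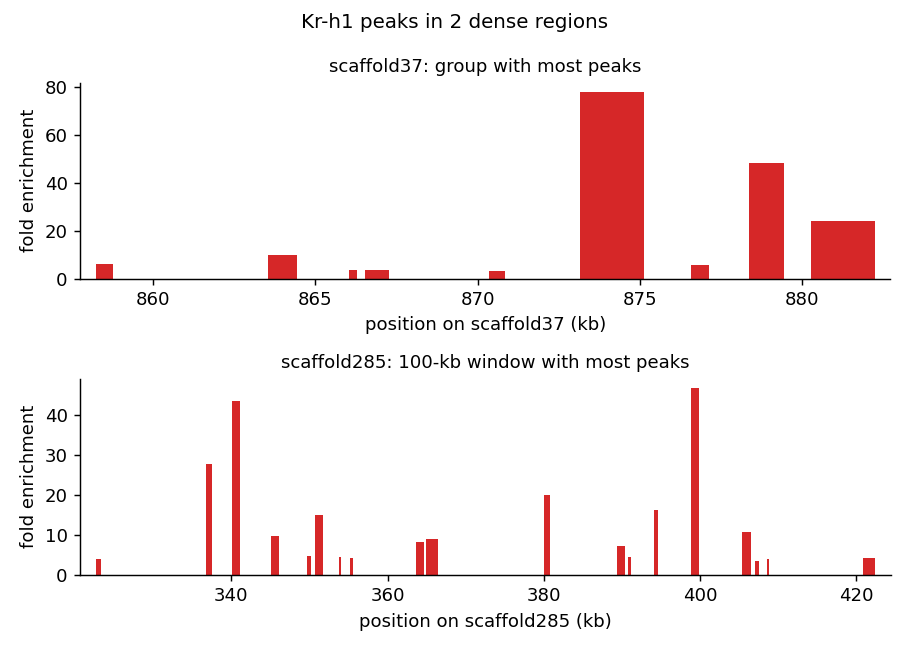
Peaks drawn to scale along the scaffold (horizontal axis, kb) with the authors' fold enrichment as bar height, for the group with most peaks (scaffold37, upper panel) and the 100-kb window with most peaks (scaffold285, lower panel). The scaffold37 group has 9 peaks with 1 of fold 77.7, and the scaffold285 window has 19 peaks with a highest fold of 46.8.

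Neighbouring peaks resembled each other in strength over short distances. The rank correlation of fold between neighbours was 0.26 for 401 pairs under 1 kb apart, 0.20 for 669 pairs 1 to 5 kb apart and 0.14 for 1273 pairs 5 to 20 kb apart. Shuffling the folds within scaffolds gave 95% ranges with upper limits of 0.14, 0.11 and 0.09 for these bands. Each band had a permutation p of 0.002, or 0.00267 after Benjamini-Hochberg adjustment over the 4 bands tested. For 1682 pairs 20 to 100 kb apart the correlation was 0.01, inside the shuffled range (adjusted permutation p of 0.282). Over the whole list the difference in strength between grouped and solitary peaks did not pass the test: the median fold was 4.85 for the 1878 peaks with a neighbour within 5 kb and 4.67 for the other 3155 (permutation p of 0.102). The call changed in a subset. Among the 4222 peaks whose folds are whole multiples of a common step, the medians were 5.06 and 4.70 (permutation p of 0.006). It also changed with a limit of 2 kb, where they were 4.95 and 4.67 (permutation p of 0.048). Over the whole list, a fold of 10 was reached by 18.4% of peaks with a neighbour within 5 kb and 19.0% of the others, and their median widths were 690 and 689 bp.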

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

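No paired analysis was possible because the peak list carries no value per sample, so the replicate numbers shared by the castes cannot enter a model, and no replicate could be left out. Also not run, for want of values per sample or an annotation and sequence of the peaks' assembly, were the alternatives fixed beforehand on peak location, distance to transcription starts, genes and gene lists, GC content, short sequences and caste. Those fixed beforehand that could be run changed the size and make-up of the list. The number of peaks was 2523 at or above the median fold and 1000 in the strongest set, and the median width was 784 and 868 bp. Merging peaks less than 500 bp apart moved the median width to 704 bp and kept 4815 peaks. Of the alternatives added after seeing the data, merging at 1 kb gave a median width of 723 bp, a fold of 10 or more gave 946 peaks with a median width of 860.5 bp, and scaffolds with 20 or more peaks held 3183. The excess of short gaps kept its direction and a permutation p of 0.002 in all 11 alternatives run. The closest to random placement was the list merged at 500 bp with scaffolds broken at gaps over 100 kb, at 22.4% against 18.02% ± 0.549. The correlation of width and fold stayed positive in the 7 subsets run, from 0.15 to 0.40. The median fold of grouped peaks passed 0.05 in 2 of 5 alternatives: 4.95 for a neighbour within 2 kb (permutation p of 0.048) and 5.06 for peaks on the common fold step described under the other observations (p of 0.006); the p ranged from 0.006 to 0.987 and the cause was not tested. Depth limits are unknown, since the list gives no reads.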

Other observations

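The spacing, neighbour and step analyses were themselves chosen after seeing the data. The main tests of explanations for spacing and neighbours, and of a second step, were set out before the results of those tests were seen. Chosen after those results were the tests of fold off the step, of repeated values and of close pairs off the step. The tests of peaks on the step alone and of the 2 kb limit were also chosen then. The spacing and neighbour patterns were both found and tested on the same list.

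The fold enrichments are not spread evenly: 4222 of the 5033 values (83.9%) are whole multiples of 0.03013 within 0.00002, where chance gives 0.133%. The multiples run from 100 to 3192. The step was fitted through 0, so that the line through them meets 0 is no separate evidence. MACS2 reports fold as reads piled up plus 1 over background plus 1, so a candidate explanation is a common background of 32.2 for most peaks, since 1/0.03013 is then background plus 1, and a higher local background for the rest. Lower folds off the step were taken as its prediction. The median there was 4.41 against 4.81 on it, below the shuffled range of 4.47 to 4.76 (permutation p of 0.014). A higher background need not lower the fold where the reads rise with it, so this result does not settle the explanation. If the reading of a common background holds, the strongest peak rests on about 3192 piled-up fragments and the weakest on the step on about 100. Separate calls, such as 1 per caste, merged into 1 list would leave a second step. The best second step, 0.03003, held 4.23% of the 331 off-step values searched. Random values gave 1.80% on average and 1.84% at most. The share of 4.23% lies above all the random lists but between the bounds set beforehand for and against separate calls, so it does not decide. A second call like the first as the source of most off-step values is argued against, since 3.95% of these repeated among themselves, against at least 73.7% in equal draws of on-step values; a small contribution stays open.

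Peaks sat closer together than random placement gave, and 3 technical explanations were tested. Splitting of wide regions into pieces less than 500 bp apart was argued against as the whole cause. After merging at 500 bp, 19.3% of gaps were still under 5 kb against at most 11.9% in the placements. After merging at 1 kb the share was 15.8% against at most 10.4%. The ratio to placement fell from 1.94 to 1.81 and 1.72 with these merges, and splitting into pieces further apart was not covered. Crowding by long stretches without peaks was argued against as the whole cause, since with scaffolds broken at gaps over 100 kb the share was 26.6% against at most 21.8%, though the ratio to placement fell from 1.94 to 1.31. If an off-step fold marks raised local background, as in sequence with extra copies, that cause predicts more off-step peaks in groups. Grouped peaks had fewer, 13.7% against 17.5% for the others. Shuffles within scaffolds gave grouped peaks 13.8 to 16.2%, and the permutation p of 0.04 sets the 13.7% against these shuffles only. Off-step peaks did adjoin each other, in 4.39% of close pairs against at most 4.30% in shuffles (permutation p of 0.002), and the marker itself is a hypothesis, so raised background stays open; the excess among on-step peaks alone was 22.0% against at most 11.98%. Uneven mappability on scales under 100 kb and uneven density of genes or regulatory sequence stay open, and no biological explanation was tested.

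Neighbours resembled each other in fold, and adjacent parts of 1 wide bound region may explain this at short range. It predicts no resemblance beyond such regions, but the rank correlation at gaps of 5 to 20 kb was 0.14, above the shuffled limit of 0.09. A shared regional property, such as open chromatin or local copy number, stays open and was not tested. That fold is unrelated to having a neighbour within 5 kb was not excluded over the whole list, with a median of 4.85 in a shuffled range of 4.67 to 4.85. It depends on the peaks and the limit used: among peaks on the common step the median was 5.06, above the shuffled range of 4.73 to 4.97 (permutation p of 0.006), and with a limit of 2 kb it was 4.95 (p of 0.048).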
